A study of Rattus norvegicus with 44 samples.

How the data were processed

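The samples were 44 cultures of 5 clonal rat neural precursor lines, each hybridised to 1 Affymetrix array. Per the labels' protocols, the clones grew on poly-lysine and laminin in medium with FGF2 and were differentiated in medium with B27 supplement and a small amount of fetal bovine serum but no FGF2. Total RNA was extracted with Trizol, and biotin-labelled targets were made with Affymetrix reagents, per the labels' protocols. Groups were the combinations of clone and day given by the sample titles. Replicates were sister cultures, per the design text of the series, so p-values measured the spread between cultures of one clone. L2.2 at day 0 had 2 arrays, since 1 array failed per the same text.

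The deposited table held 1 intensity per probe set and array, made by the authors with GCOS, the scanner software, and RMA, a method that corrects, normalizes and summarises probe signals, per the submitters' processing notes. Versions and settings of both were not given in the sources used here. The design had assumed log2 values, but the intensities were linear, from 6.39 to 12734, so log2 was taken without a pseudocount. Array medians of 24.2 to 28.9 and upper quartiles of 151 to 163 lay close together, so no further normalization was applied. The medians nevertheless went with the day, at most 26.2 at day 0 and at least 26.8 at day 7. Shifting all arrays to one median moved the median day 7 change of all genes by between -0.105, in L2.3, and -0.164, in Ctx8. RMA scales the arrays to each other, and a change in the total amount of RNA per cell would not show. No 2 arrays had identical values. Detection calls, scan dates and batches were not used here, so a batch effect could not be tested.

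Of 24183 probe sets, 17547 had exactly 1 gene in the platform annotation, 213 had several and 6423 were unnamed. Symbols were updated through gene IDs for 17450 probe sets, and 97 kept the platform symbol. The probe set with the highest mean over all arrays stood for its gene, which gave 12749 genes, 3498 of them with more than 1 probe set. Among the 287 pairs of named gene and comparison, other probe sets of the gene gave 134 results. Of these 117 made the same call, 0 the opposite call and 17 passed where the chosen one did not, or the reverse. The latter concerned Clu, Dpysl3, Hes5, Igf2, Mmp2, Nrarp, Otx2, Serpinf1, Serpinh1, Slc1a3 and Tubb3, whose other probe sets had mean intensities between 10.1 and 22.5.

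One linear model with a mean for each of the 15 groups was fitted with limma (lmFit and eBayes), which left 29 residual degrees of freedom, 5.00 prior degrees of freedom and a median residual SD of 0.122 in log2. Contrasts compared days 3 and 7 with day 0 in each clone, Ge6 with the equally weighted mean of the 4 other clones at each day, Ge6 with L2.2 at days 0 and 7, Ge2 with the other clones at day 7 and Ctx8 with L2.3 at day 0. The day 7 change of Ge6 was compared with the mean change of the other clones, and an F test asked whether it differed between any clones. Two-sided p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, a gene was called at an adjusted p under 0.05, and called genes with at least a 2-fold change were counted as well.

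The 20 gene lists covered Dlx and ventral forebrain factors, GABA and interneuron genes, GABA-A receptors, pan-neuronal genes, glutamate receptors and channels, glutamatergic and dorsal forebrain genes, neural precursors, the cell cycle, astrocytes, oligodendrocytes, FGF and ERK targets, Notch, BMP and TGF-beta, cholesterol synthesis, mesenchymal and matrix genes, microglia, endothelium, Schwann and neural crest cells, interferon and stress. Members without a probe set of a single gene were not analysed here, which left 9 of 21 for the Dlx list. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the 20 lists of a comparison. Comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. Named could be Dlx1, Dlx2, Dlx5, Dlx6, Gad1 and Gad2 anywhere. Per comparison, the 10 largest rises and falls could be named, among called genes whose arrays did not overlap between the sides, a demand not made of differences between changes. Per list and comparison, up to 3 members with the largest rise, 3 with the largest fall past the threshold and the 2 brightest members that did not pass could be named.

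Alternatives were quantile normalization, shifting all arrays to one median, leaving out dim genes (no group mean above 16.3, the 40th percentile of all values), the mean of a gene's probe sets, every probe set on its own, array weights, a variance trend with robust estimation, a minimum fold in the test, fits to only the groups compared, the replicate number as a block, an estimated correlation and leaving out each array. The pipeline was tested on simulated data with the spread of 12749 genes, where the day 7 means of each clone were set to those of day 0. Changes were then put into a small part of the genes in Ge6 at day 7, with independent noise per gene. In the data 58.9% of genes were called there, so the rates that follow need not hold for the data. For day 7 against day 0 in Ge6 it called 40% of 1.25-fold, 90% of 1.5-fold and 100% of 2-fold changes, 50 genes each, and 5 of 12519 unchanged genes. For the difference of day 7 changes in Ge6 it called 30%, 84% and 100%. Analyses were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.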

Results

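Messenger RNA levels were measured on Affymetrix oligonucleotide arrays in 5 clonal lines of rat neural precursor cells. The cells were kept dividing with FGF2, a growth factor for neural precursors. They were collected at day 0, before the growth factor was withdrawn, and at days 3 and 7 of differentiation without it, in medium with a little serum. By its label, Ge6 is a GABAergic neuronal precursor, L2.2 an interneuronal precursor and Ge2 a nonneuronal precursor, while Ctx8 and L2.3 are multipotential. Each of the 15 combinations of clone and day had 3 sister cultures on 1 array each, except L2.2 at day 0 with 2, which gave 44 arrays. The sister cultures came from a single clone, so the tests measured the spread between cultures, and every difference between clones was one between single clones rather than between precursor types. The median intensity of an array lay between 24.2 and 28.9, and the number of arrays limits the precision. Detection calls were not used here, and in 84 of 206 named differences between 2 groups the lower mean lay under 16.3, the 40th percentile of all values, near background, so the size of such a difference is uncertain beyond its SE. Changes are given in log2 ± SE from the limma fit and levels as mean intensity ± SD, and genes were called by their Benjamini-Hochberg adjusted p. An adjusted p beside a gene list is that of camera, limma's test of a list against all other genes with a preset correlation. Where the call of a list was lost with a correlation estimated from the data, that p is given as well.

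Sister cultures were close to each other. Over the 24183 probe sets, Pearson's r across probe sets, which are not independent replicates, was 0.992 to 0.998 for the 43 pairs of arrays within a group and 0.876 to 0.992 for the 903 pairs between groups. The first principal component of the same probe sets took 32.4% of the variance and placed every day 0 array below every day 3 and day 7 array of its clone. The second took 23% and placed all arrays of Ge2 above those of the 4 other clones.

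**Figure D1:**
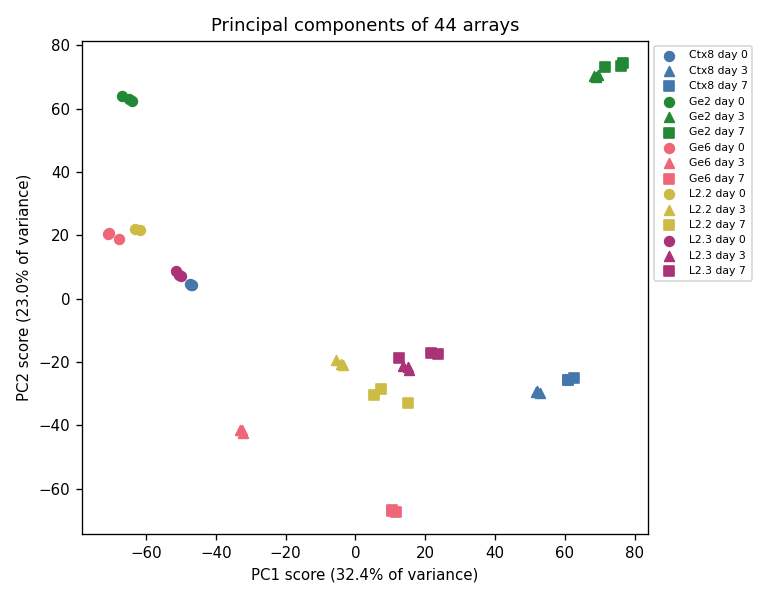
Scores of the 44 arrays on the first 2 principal components of log2 intensity, with 32.4% and 23% of the variance; colour marks the clone and symbol the day. Arrays of most groups lie together, but replicate 1 of L2.3 at day 7 lies nearer to L2.3 at day 3 than to its sister arrays. Ge2 lies apart from the other clones on the second component.

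The title of the series asks about Dlx factors in a clone that gives GABAergic neurons. Dlx1 and Dlx5 are homeobox factors of the ventral forebrain, where GABAergic neurons arise, and Gad1 and Gad2 are the enzymes that make GABA. In Ge6, Dlx1 had a mean intensity of 156 ± 13.1 (SD, n = 3) at day 0, 1903 ± 71 at day 3 and 2457 ± 157 at day 7. Dlx5 in Ge6 went from 125 ± 15.3 through 1069 ± 32.1 to 867 ± 16.1. Gad1 in Ge6 went from 12.3 ± 1.5 to 1708 ± 31 and 2989.5 ± 178, and Gad2 from 15.5 ± 1.4 to 253 ± 28.2 and 395 ± 11. From day 0 to day 7 the log2 change in Ge6 was 3.97 ± 0.17 for Dlx1, 2.80 ± 0.19 for Dlx5, 7.93 ± 0.13 for Gad1 and 4.67 ± 0.11 for Gad2, with adjusted p of 5.7e-21, 3e-15, 1.3e-32 and 3.47e-28. The day 0 means of Gad1 and Gad2 lay under 16.3, so the sizes of these 2 changes rest on a start near background. Dlx2 and Dlx6 were not analysed here.

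The 4 other clones had other combinations of these genes. In L2.2, Dlx1 rose from 248 ± 10.5 (SD, n = 2) at day 0 to 1204 ± 99.2 at day 7, by 2.27 ± 0.19, and Dlx5 rose there from 29.7 ± 2.5 to 809 ± 64.8, a log2 change of 4.76 ± 0.22. In Ctx8, Dlx1 rose from 17.7 ± 2.7 to 566 ± 27, by 5.0 ± 0.17 in log2, and Dlx5 reached 102 ± 11.5. Ge2 had little Dlx1, 14.9 ± 4.4 at day 7 with a log2 change of -0.08 ± 0.17, yet its Gad1 rose from 9.3 ± 2.0 to 606 ± 24.9 at day 3 and 877 ± 62.1 at day 7, by 6.58 ± 0.13. Gad1 also rose by 4.80 ± 0.14 in L2.2, to 252 ± 21.4, and by 3.64 ± 0.13 in Ctx8, to 98.8 ± 12.2. The other Gad1 probe set rose less, by 1.05 in L2.2, 0.46 in Ctx8 and 2.55 in Ge2, against 5.61 in Ge6. The size of the Gad1 rise in these clones thus depends on the probe set. At day 7 L2.3 had 16.6 ± 1.4 for Dlx1, 10.5 ± 3.9 for Dlx5, 8.7 ± 0.8 for Gad1 and 11.1 ± 0.8 for Gad2, and its log2 change of Gad1 was 0.05 ± 0.13. Gad2 outside Ge6 was highest in Ge2, at 43.2 ± 6.0. The day 7 change of Gad1 was larger in Ge6 than the mean change of the 4 other clones by 4.16 ± 0.14 in log2, with an adjusted p of 6.38e-23. For Gad2 that difference was 3.96 ± 0.13, for Dlx1 2.12 ± 0.19 and for Dlx5 0.83 ± 0.22. Dlx1 changed more in Ctx8 than in Ge6, by a difference of -1.03, and Dlx5 more in L2.2, by -1.97, and in Ctx8, by -0.36, differences that were not tested singly. Dlx5 in Ctx8 rose from 11.4 ± 0.7, near background, so the size of its change is uncertain. The day 7 levels of both genes in Ctx8 lay below those of Ge6.

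**Figure D2:**
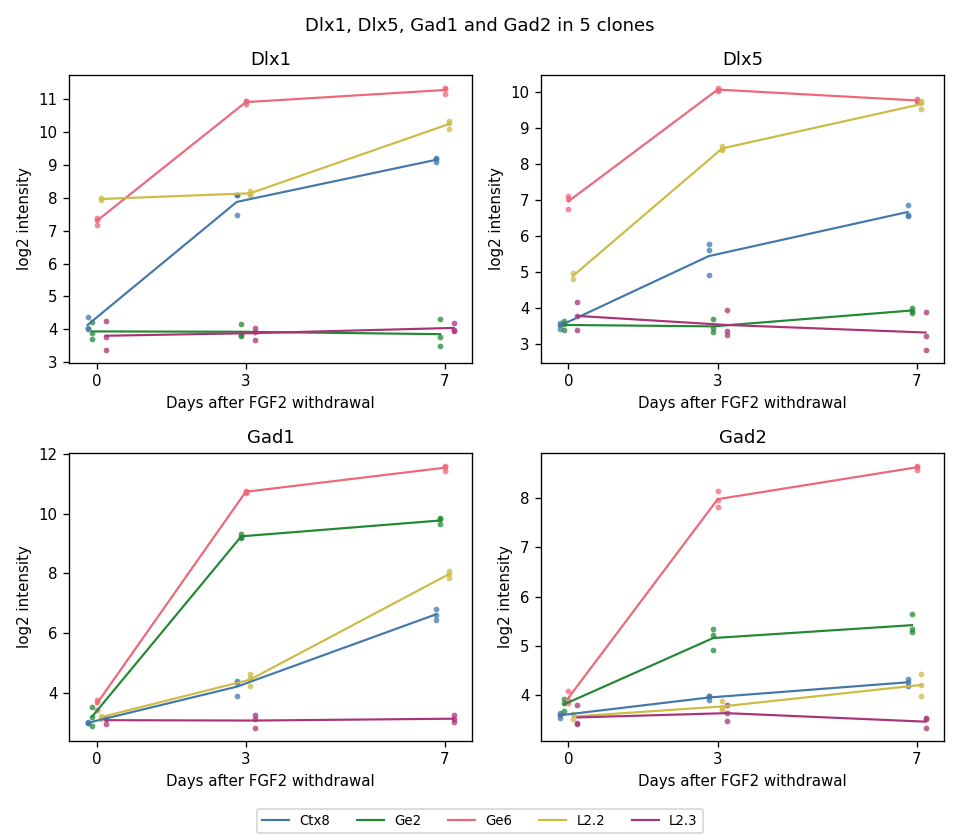
Log2 intensity of Dlx1, Dlx5, Gad1 and Gad2 at days 0, 3 and 7 after FGF2 withdrawal in the 5 clones; points are single arrays and lines join the group means. Ge6 has the highest means at day 7, 2457, 867, 2989.5 and 395, though its Dlx5 lies within error of that of L2.2.

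Day 3 in Ge6 brought neuronal genes, while 23 of 38 cell cycle genes did not pass the test. Of the 37 measured pan-neuronal genes 31 rose and 0 fell (adjusted p = 9.25e-19), led by the microtubule proteins Stmn4 (4.91 ± 0.10), Dcx (4.70 ± 0.15) and Stmn3 (4.42 ± 0.16). In the list of GABA synthesis, transport and interneuron genes 9 of 15 rose (adjusted p = 0.000304). These included Gad1, by 7.12 ± 0.13, and the vesicular GABA transporter Slc32a1, by 3.65 ± 0.16, while the calcium-binding protein Calb2 (-3.47 ± 0.15) fell. Among the 9 measured genes of the list of Dlx and ventral forebrain factors 7 rose (adjusted p = 6.83e-06). This list holds the family named in the title of the series, so it is not independent evidence. The factors Bcl11b (4.72 ± 0.17) and Runx1t1 (4.71 ± 0.18) and the cannabinoid receptor Cnr1 (6.06 ± 0.14) were among the 10 largest rises. Targets and feedback regulators of FGF and ERK signalling fell in 9 of 16 cases (adjusted p = 0.000321), with Dusp6 (-4.69 ± 0.11), Etv5 (-4.66 ± 0.15) and Spry2 (-4.05 ± 0.10). The oligodendrocyte lineage factors Olig1 (-4.20 ± 0.16) and Olig2 (-3.57 ± 0.18) fell as well. Of the cell cycle genes 12 fell and 3 rose, with a median change of -0.14 (adjusted p = 0.671). In all, 6245 genes were called, 2605 higher and 3640 lower, and 1294 of them changed at least 2-fold. The highest adjusted p among genes named here as risen or fallen was 6.31e-19, for Olig2.

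At day 7, Ge6 had raised most of its neuronal genes and reduced its cell cycle genes. Pan-neuronal genes rose in 36 of 37 cases with a median log2 change of 3.29 (adjusted p = 4.02e-24), among them tau, Mapt (7.31 ± 0.14), Stmn3 (6.56 ± 0.16) and Stmn4 (6.39 ± 0.10). Voltage-gated channels and glutamate receptors rose in 17 of 27 cases (adjusted p = 5.89e-07), led by the sodium channel subunits Scn3b (3.74 ± 0.12) and Scn1a (3.60 ± 0.17) and the potassium channel Kcnd2 (3.06 ± 0.18). In the GABA and interneuron list 10 rose and 1 fell of 15 (adjusted p = 4.26e-05). The risers included Slc32a1 (4.92 ± 0.16) and neuropeptide Y, Npy (4.86 ± 0.12), and Calb2 (-3.43 ± 0.15) was the member that fell. Of the GABA-A receptor subunits, 2 of 9 rose, Gabrg1 (0.88 ± 0.20) and Gabrg3 (0.23 ± 0.09) (adjusted p = 0.483). Gabrg3 lost its call when 1 array was left out, with 0.19 and 0.21 without replicate 1 or 3 of day 0 and 0.20 and 0.20 without replicate 2 or 3 of day 7, and it was at 0.08 with all arrays shifted to one median. Its call was also lost in limma with array weights (0.22, adjusted p = 0.0661) and with a 1.2-fold minimum in the test. The homeobox factor Meis2 (3.08 ± 0.07) rose with Dlx1 and Dlx5, and 7 of 9 members of that list rose (adjusted p = 0.000192). All 38 of 38 cell cycle genes fell, by a median of -1.27 (adjusted p = 1.97e-08, but adjusted p = 0.208 with an estimated correlation), with Tk1 (-2.97 ± 0.10), Mcm3 (-2.39 ± 0.14) and Mcm2 (-2.31 ± 0.09). Astrocyte genes rose in 11 of 20 cases (adjusted p = 0.000904, but adjusted p = 0.169 with an estimated correlation), including the water channel Aqp4 (5.96 ± 0.21), Apoe (5.54 ± 0.20) and Clu (5.47 ± 0.14). The cholesterol synthesis genes fell in 17 of 18 cases (adjusted p = 9.96e-07, but adjusted p = 0.106 with an estimated correlation), such as Mvd (-2.78 ± 0.11) and Hsd17b7 (-2.38 ± 0.13). Stress response genes fell in 9 of 14 cases (adjusted p = 0.0446, but adjusted p = 0.0721 with an estimated correlation), with Chac1 (-3.29 ± 0.19) and Trib3 (-3.28 ± 0.12) ahead. The adjusted p of that list was 0.0504 without replicate 2 and 0.0533 without replicate 3 of day 7, 0.0512 after quantile normalization and 0.118 without dim genes. Of the FGF and ERK targets 8 fell and 4 rose (adjusted p = 0.142). There Etv5 (-4.48 ± 0.15) and cyclin D1, Ccnd1 (-4.46 ± 0.15), fell, and Myc (2.74 ± 0.14) rose. The fit called 7511 genes, 3054 higher and 4457 lower (2488 and 6299 with all arrays shifted to one median), and 2691 of them changed at least 2-fold. The highest adjusted p among the genes named as changed was 0.039, for Gabrg3.

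L2.2, the interneuronal precursor, also took up neuronal genes, together with glial genes and some members of the glutamatergic and dorsal forebrain list. At day 3 pan-neuronal genes had risen in 34 of 37 cases (adjusted p = 1.4e-27), with Dcx (5.95 ± 0.17), Mapt (5.67 ± 0.16) and Stmn2 (4.90 ± 0.15). The interneuron markers Reln (4.36 ± 0.18), Calb2 (4.14 ± 0.17) and Sst (2.15 ± 0.16), which are reelin, calretinin and somatostatin, led 9 rises of 15 in the GABA and interneuron list (adjusted p = 6.4e-05). Dlx5 rose by 3.54 ± 0.22, and Dlx1 had a change of 0.17 ± 0.19 at that day, which did not pass the test (adjusted p = 0.502). In the list of glutamatergic and dorsal forebrain genes 5 of 13 rose and 3 fell (adjusted p = 0.0193). The risers were Lhx2 (4.75 ± 0.10), the vesicular glutamate transporter Slc17a6 (4.07 ± 0.16), Neurod1 (3.00 ± 0.14) and others, the median change was -0.002 and the mean was 0.97. Cell cycle genes fell in 29 of 38 cases by a median of -0.70 (adjusted p = 4.42e-05, but adjusted p = 0.352 with an estimated correlation). Genes of the stress response fell in 8 of 14 cases (adjusted p = 0.00112). The largest falls were Trib3 (-5.10 ± 0.13) and Chac1 (-4.53 ± 0.21), induced when amino acids run short, and the transcription factor Ddit3 (-3.48 ± 0.17). The amino acid transporters Slc7a3 (-3.92 ± 0.16) and Slc1a5 (-3.84 ± 0.17) fell with them. Notch pathway genes rose in 6 of 14 cases, Notch1 (2.79 ± 0.09) and Hey1 (2.42 ± 0.11) most (adjusted p = 0.00571). The count was 6049 genes, 2515 higher and 3534 lower (1890 and 5338 with all arrays shifted to one median), 1176 of them at least 2-fold. Among named changes that passed, the highest adjusted p was 8.56e-14, for Sst.

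By day 7 the pan-neuronal genes of L2.2 had risen in 35 of 37 cases (adjusted p = 1.57e-27) and its astrocyte genes in 15 of 20 (adjusted p = 3.26e-12). Largest were Dcx (6.83 ± 0.17) and Mapt (6.07 ± 0.16) among the former and Gfap (6.74 ± 0.18), Aqp4 (6.52 ± 0.23) and Apoe (6.15 ± 0.22) among the latter. Reln and Calb2 were above day 0 by 5.91 ± 0.18 and 5.39 ± 0.17. The oligodendrocyte precursor receptor Pdgfra (4.97 ± 0.13) and Bcas1 (3.15 ± 0.29) rose in the oligodendrocyte list (adjusted p = 0.00681, but adjusted p = 0.175 with an estimated correlation). The list of neural precursor and radial glia genes rose in 9 and fell in 5 of 14 cases (adjusted p = 0.00133), with Fabp7 (2.94 ± 0.09) and Slc1a3 (2.40 ± 0.10) up and Prom1 (-1.30 ± 0.14) and Pax6 (-1.07 ± 0.11) down. Cholesterol synthesis genes, whose test pointed downward in the 4 other clones, were higher in 9 and lower in 3 of 18 cases (adjusted p = 0.0242, but adjusted p = 0.417 with an estimated correlation). Without dim genes the adjusted p of that list was 0.0554. Idi1 changed by 1.01 ± 0.10 and Lss by 1.01 ± 0.09. At day 0 the median intensity of that list was 199.9 in L2.2 and 668, 371, 423 and 673 in Ctx8, Ge2, Ge6 and L2.3. A total of 6601 genes were called, 2733 higher and 3868 lower (2188 and 5316 with all arrays shifted to one median), and 1565 changed at least 2-fold. Named changes had adjusted p of at most 7.51e-10, for Prom1, and day 0 rested on 2 arrays.

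Ge2, the nonneuronal precursor, lost cell cycle transcripts. At day 3 all 38 of 38 cell cycle genes had fallen, by a median of -4.88 (adjusted p = 1.7e-24), with the ribonucleotide reductase subunit Rrm2 (-7.35 ± 0.30), Ube2c (-6.68 ± 0.26) and cyclin B1, Ccnb1 (-6.37 ± 0.22). Astrocyte genes rose in 12 of 20 cases (adjusted p = 6.8e-05, but adjusted p = 0.0792 with an estimated correlation), with Apoe (5.80 ± 0.20), Gfap (5.73 ± 0.16) and Atp1b2 (5.40 ± 0.15), but the gap junction protein connexin 43, Gja1 (-5.82 ± 0.10), fell. BMP and TGF-beta responsive genes rose in 9 of 13 cases (adjusted p = 0.000599), with Id2 (4.42 ± 0.11), Id4 (3.85 ± 0.11) and Bambi (2.95 ± 0.12). Of the pan-neuronal genes 6 rose and 7 fell of 37 (adjusted p = 0.841). Within that list Nsg2 (3.39 ± 0.12) was highest and Crmp1 (-1.52 ± 0.07) lowest. Gad1 rose by 6.05 ± 0.13 from a day 0 mean near background, and Reln (4.53 ± 0.16) rose, and 4 of 15 genes of the GABA list were higher (adjusted p = 0.103). Stress response genes fell in 9 of 14 cases (adjusted p = 0.00639), Chac1 (-5.71 ± 0.19) and Trib3 (-3.43 ± 0.12) among them, and the mitochondrial folate enzyme Mthfd2 (-6.20 ± 0.12) fell too. The fit called 7644 genes, 3510 higher and 4134 lower (2814 and 5978 with all arrays shifted to one median), with 2743 changed at least 2-fold. Among named changes the highest adjusted p was 1.8e-20, for Crmp1.

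At day 7 in Ge2, cell cycle genes were lower than at day 0 in 38 of 38 cases, by a median of -4.62 (adjusted p = 2.34e-23), and FGF and ERK targets in 11 of 16 (adjusted p = 0.00234), with Dusp6 (-5.92 ± 0.11) and Etv5 (-4.72 ± 0.15). Apoe had risen by 7.77 ± 0.20, S100b by 6.15 ± 0.15 and Gfap by 5.75 ± 0.16. The matrix protein Ogn, osteoglycin, had risen by 6.71 ± 0.11 and periostin, Postn (2.61 ± 0.08), rose in the list of mesenchymal, pericyte and matrix genes, where 8 of 19 were higher (adjusted p = 0.16). Interferon and antigen presentation genes rose in 9 of 19 cases (adjusted p = 0.0271, but adjusted p = 0.0646 with an estimated correlation), among them Rsad2 (2.29 ± 0.11) and Irf1 (1.78 ± 0.13). Without the 3 arrays farthest from their group means, all of Ge2 and chosen after seeing the data, that adjusted p was 0.0522. Pan-neuronal genes rose in 8 and fell in 8 of 37 cases (adjusted p = 0.827), and their median intensity was 15.2 in Ge2 against 394 in Ge6. The count was 7692 genes, 3443 higher and 4249 lower (2917 and 6129 with all arrays shifted to one median), and 2801 of them changed at least 2-fold. Named changes had adjusted p of at most 8.71e-15, for Irf1.

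Ctx8, a multipotential clone, turned on glial genes of both kinds. At day 3 the myelin genes Mbp (7.69 ± 0.18) and Cldn11 (5.43 ± 0.18) and the oligodendrocyte factor Nkx2-2 (4.22 ± 0.20) had risen, with 11 of 18 oligodendrocyte lineage genes higher (adjusted p = 0.00045, but adjusted p = 0.0812 with an estimated correlation). Aqp4 rose by 6.47 ± 0.21, Apoe by 5.30 ± 0.20 and Mlc1 by 5.14 ± 0.18, and 13 of 20 astrocyte genes were higher (adjusted p = 1.8e-06). BMP and TGF-beta responsive genes rose in 10 of 13 cases (adjusted p = 6.15e-05), including Bmp4 (5.49 ± 0.24) and the inhibitors of differentiation Id4 (4.22 ± 0.11) and Id3 (4.01 ± 0.10). Some neuronal genes rose as well, 20 of 37 (adjusted p = 1.89e-05), with Dcx (4.87 ± 0.15) and Dpysl3 (4.30 ± 0.19). The cell cycle list fell in 38 of 38 cases (adjusted p = 1.01e-17, but adjusted p = 0.069 with an estimated correlation). Of all genes 6839 were called, 3048 higher and 3791 lower (2506 and 5917 with all arrays shifted to one median), and 1841 changed at least 2-fold. Among named changes the highest adjusted p was 1.92e-19, for Nkx2-2.

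At day 7 in Ctx8, 17 of 20 astrocyte genes were higher, with a list median of 3.18 (adjusted p = 3.51e-12). Aqp4 had risen by 8.29 ± 0.21, Apoe by 7.95 ± 0.20 and Gfap by 6.70 ± 0.16, beside Mbp (7.16 ± 0.18) and Bmp4 (6.08 ± 0.24). Of the GABA and interneuron genes 8 of 15 rose (adjusted p = 0.00922), with Reln (2.85 ± 0.16) and the GABA-degrading enzyme Abat (2.17 ± 0.12) next to Gad1. Pan-neuronal genes rose in 21 of 37 cases (adjusted p = 1.59e-05). The cholesterol synthesis genes fell in 18 of 18 cases by a median of -1.43 (adjusted p = 8.56e-10). FGF and ERK targets fell in 10 of 16 cases (adjusted p = 0.00163), with Spry1 (-4.15 ± 0.12) and Dusp6 (-4.04 ± 0.11), and the precursor filament protein nestin, Nes (-2.47 ± 0.10), fell. The fit called 7123 genes, 3178 higher and 3945 lower (2530 and 6447 with all arrays shifted to one median), and 2065 changed at least 2-fold. Named changes had adjusted p of at most 2.43e-17, for Abat.

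L2.3, the other multipotential clone, combined neuronal and glial genes. At day 3 tubulin beta 3, Tubb3 (6.08 ± 0.08), Stmn2 (6.05 ± 0.13) and Dcx (5.22 ± 0.15) led 26 rises among 37 pan-neuronal genes (adjusted p = 1.99e-16). Mbp rose by 6.82 ± 0.18, Apoe by 6.60 ± 0.20 and Aqp4 by 6.24 ± 0.21. The glutamatergic genes Slc17a6 (4.46 ± 0.14) and Neurod1 (4.27 ± 0.13) rose, and 6 of 13 genes of their list were higher (adjusted p = 0.00134). FGF and ERK targets fell in 10 of 16 cases by a median of -2.38 (adjusted p = 7.06e-08), with Dusp6 (-5.14 ± 0.11), Etv5 (-4.23 ± 0.15) and Ccnd1 (-4.10 ± 0.15). Oligodendrocyte genes rose in 9 and fell in 4 of 18 cases (adjusted p = 0.0242, but adjusted p = 0.296 with an estimated correlation), the falls being of the precursor genes Cspg4 (-2.34 ± 0.15), Olig2 (-1.89 ± 0.18) and Olig1 (-1.29 ± 0.16) and 1 other. Calls numbered 5892, 2546 higher and 3346 lower (2111 and 4519 with all arrays shifted to one median), and 1055 of them were at least 2-fold. Among named changes the highest adjusted p was 3.03e-08, for Olig1.

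At day 7 in L2.3, Gfap (8.23 ± 0.16), Aqp4 (8.19 ± 0.21) and Apoe (8.17 ± 0.20) were the largest rises, and 16 of 20 astrocyte genes were higher (adjusted p = 1.49e-14). Pan-neuronal genes were higher in 29 of 37 cases (adjusted p = 5.39e-18). Slc17a6 had risen by 4.93 ± 0.14 and Neurod1 by 4.69 ± 0.13 (adjusted p = 0.0144 for the list), and calbindin, Calb1 (4.29 ± 0.17), led 5 rises among 15 GABA and interneuron genes (adjusted p = 0.0303, but adjusted p = 0.057 with an estimated correlation), and that p was 0.0511 without dim genes. BMP and TGF-beta responsive genes rose in 8 of 13 cases (adjusted p = 0.000195), with Id4 (4.15 ± 0.11) and Bmp4 (3.32 ± 0.24). Cholesterol synthesis genes fell in 18 of 18 cases (adjusted p = 6.42e-10) and cell cycle genes in 32 of 38 (adjusted p = 6.42e-10, but adjusted p = 0.207 with an estimated correlation). The stress list had 4 higher and 5 lower of 14 genes (adjusted p = 0.977), with Hmox1 (1.63 ± 0.16) up and Cdkn1a (-1.85 ± 0.11) down. The count was 6224 genes, 2794 higher and 3430 lower (2276 and 5063 with all arrays shifted to one median), 1267 of them at least 2-fold. Named changes had adjusted p of at most 1.32e-10, for Hmox1.

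**Figure D3:**
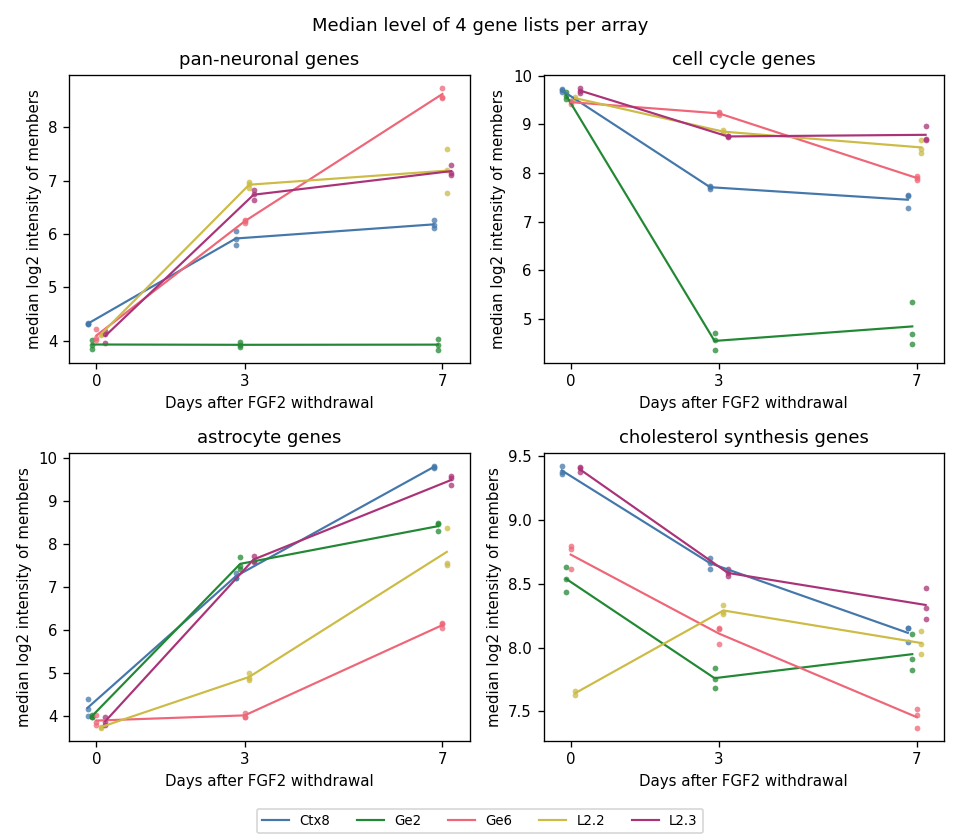
Median log2 intensity over the members of 4 gene lists at days 0, 3 and 7 after FGF2 withdrawal in the 5 clones; points are single arrays and lines join the group means. Pan-neuronal genes end highest in Ge6, at a median intensity of 394 against 15.2 in Ge2 at day 7, and cholesterol synthesis genes start lowest in L2.2, at 199.9.

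**Figure D4:**
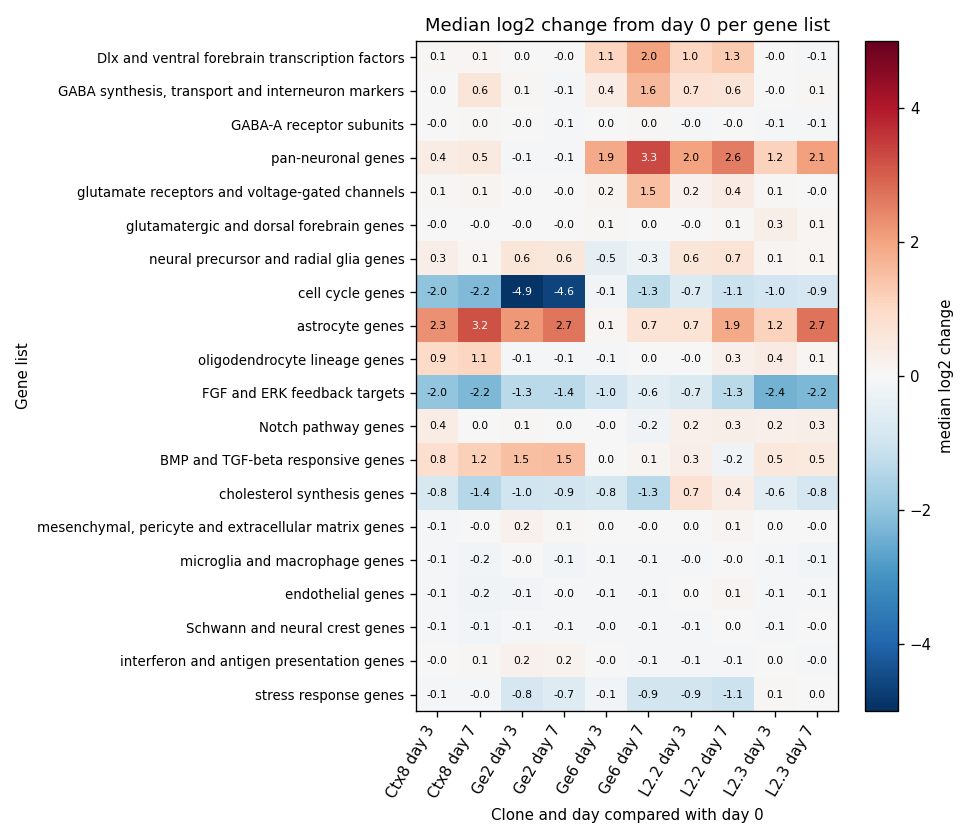
Median log2 change from day 0 over the members of each of the 20 gene lists, by clone and day; red is higher and blue lower than day 0, and each cell prints its value. The lowest value is the cell cycle list of Ge2 at day 3, -4.88, and the highest the pan-neuronal list of Ge6 at day 7, 3.29.

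Ge6 was next set against the mean of the 4 other clones at each day. That mean weights the clones equally, so 1 clone far from the rest moves it, and Ge6 was tested against a single clone only for L2.2. At day 0, still in FGF2, Dlx5 was higher in Ge6 by 3.04 ± 0.15 and Dlx1 by 2.33 ± 0.14, and 5 of 9 genes of the Dlx and ventral forebrain list were higher (adjusted p = 0.000984). The homeobox factor Otx2 (4.75 ± 0.07) and Calb2 (3.88 ± 0.12) were the largest differences upward. Pax6, a factor of dorsal progenitors, was lower, with a log2 difference of -4.37 ± 0.08, and the glycolytic enzyme Aldoc (-2.51 ± 0.07) was lower too. FGF and ERK targets were lower in 11 of 16 cases (adjusted p = 1.29e-05), with Egr1 (-1.74 ± 0.12) and Myc (-1.11 ± 0.11). Notch pathway genes were lower in 8 of 14 (adjusted p = 0.0319), with Hey1 (-1.64 ± 0.08) and Hes5 (-1.61 ± 0.13). Of the pan-neuronal genes 10 were higher and 11 lower of 37 (adjusted p = 0.956). Against L2.2 alone the means of Ge6 lay on the other side for Dlx1 (-0.67), Egr1 (0.63), Hey1 (0.26), Myc (0.64) and the median of the Notch list (0.13), and for Myc against Ge2 as well (0.65). Ge6 lay close to L2.2 for Aldoc (-0.11) and Hes5 (-0.13), and the median of the FGF and ERK list lay -0.09 from both Ge2 and L2.2. The fit called 4966 genes, 2592 higher and 2374 lower (3243 and 1965 with all arrays shifted to one median), of which 356 differed at least 2-fold. Among named differences the highest adjusted p was 1.78e-10, for Myc.

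At day 3, Ge6 was higher in all 38 of 38 cell cycle genes, by a median of 1.85 (adjusted p = 1.41e-19), with Rrm2 (2.40 ± 0.24) and Ube2c (2.35 ± 0.20). The median intensity of that list was 599 in Ge6, 462 in L2.2, 431 in L2.3, 209 in Ctx8 and 23.3 in Ge2, so most of the difference from the mean came from Ge2 and Ctx8. Gad1 was higher by 5.50 ± 0.10, Dlx1 by 4.94 ± 0.14, Dlx5 by 4.84 ± 0.15 and Gad2 by 3.85 ± 0.09. Neuropeptide Y, Npy (4.59 ± 0.09), and the neuronal factors Mef2c (4.46 ± 0.10) and Bcl11b (4.32 ± 0.14) were higher. Astrocyte genes were lower in 14 of 20 cases (adjusted p = 3.49e-07), led by Gfap (-4.58 ± 0.12) and Aldoc (-4.34 ± 0.07), and oligodendrocyte lineage genes in 13 of 18 (adjusted p = 7.42e-05). BMP and TGF-beta responsive genes were lower in 9 of 13 cases (adjusted p = 0.000204), with Id3 (-5.22 ± 0.08) and Id1 (-4.19 ± 0.09), and Notch pathway genes in 10 of 14 (adjusted p = 0.000208), with Hes1 (-2.38 ± 0.09). Pan-neuronal genes were higher in 20 and lower in 8 of 37 (adjusted p = 0.00159, but adjusted p = 0.0602 with an estimated correlation). The median intensity of the pan-neuronal list was 75.5 in Ge6, below the 121 of L2.2 and 106 of L2.3 and above the 60.3 of Ctx8 and 15.2 of Ge2. The oligodendrocyte list had median differences of -4.00 from Ctx8 and -2.12 from L2.3, but 0.09 from Ge2 and 0.11 from L2.2, and the BMP and TGF-beta list had -0.06 from L2.3. Counts came to 7176 genes, 3655 higher and 3521 lower (5880 and 2655 with all arrays shifted to one median), and 1457 of them differed at least 2-fold. Named differences had adjusted p of at most 4.43e-11, for Rrm2.

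At day 7, 34 of 37 pan-neuronal genes were higher in Ge6 than the mean of the other clones, by a median of 2.08 (adjusted p = 5.43e-19). That list had median differences of 3.38 from Ge2 and 2.07 from Ctx8, but 1.09 from L2.3 and 0.685 from L2.2. Myt1l, a neuronal factor, was higher by 4.03 ± 0.10, and the channel and glutamate receptor list was higher in 17 of 27 cases (adjusted p = 3.22e-06), with Scn1a (3.19 ± 0.14) and Gria1 (2.70 ± 0.09). The channel list had median differences of 1.3 from Ge2 and 0.693 from L2.2, but 0.299 from L2.3 and 0.221 from Ctx8. Of the GABA and interneuron genes 7 were higher and 4 lower (adjusted p = 0.0131). Npy was higher by 5.22 ± 0.09, Gad1 by 4.67 ± 0.10 and Slc32a1 by 4.31 ± 0.13, while Abat (-1.70 ± 0.10), Calb2 (-1.54 ± 0.12) and Reln (-1.43 ± 0.12) were lower. The neurokinin B gene Tac3 (5.06 ± 0.11), the receptor Npy1r (5.22 ± 0.08) and Bcl11b (4.86 ± 0.14) were among the 10 largest differences. Astrocyte genes were lower in 15 of 20 cases (adjusted p = 1.99e-06), with Agt (-4.18 ± 0.11) and Mlc1 (-3.65 ± 0.14). Notch pathway genes were lower in 9 of 14 (adjusted p = 0.000947), with Nrarp (-2.24 ± 0.11) and Notch1 (-2.19 ± 0.06). Cell cycle genes were higher in 34 of 38 (adjusted p = 1.99e-06, but adjusted p = 0.245 with an estimated correlation). The median intensity of the cell cycle list was 239 in Ge6, below the 369 of L2.2 and 441 of L2.3 and above the 175 of Ctx8 and 28.7 of Ge2. By their means, Calb2 in Ge6 lay above Ge2 (0.92), the GABA and interneuron list had a median difference of -0.02 from L2.2, and Reln lay above Ctx8 (0.73) and L2.3 (0.07). Genes called numbered 7307, 3320 higher and 3987 lower, and 1530 differed at least 2-fold. Among named differences the highest adjusted p was 2.29e-12, for Reln.

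The GABAergic and the interneuronal precursor differed before differentiation. At day 0 the retinoic acid binding protein Crabp2 (-6.46 ± 0.17), the growth factors Mdk (-6.40 ± 0.12) and Igf2 (-5.57 ± 0.12) and the imprinted RNA H19 (-4.89 ± 0.22) were lower in Ge6 than in L2.2. Otx2 was higher in Ge6, by 4.87 ± 0.10, and so were Olig1 (4.34 ± 0.18) and Olig2 (3.92 ± 0.20). Cholesterol synthesis genes were higher in Ge6 in 17 of 18 cases by a median of 1.08 (adjusted p = 1.68e-18), with Hsd17b7 (2.69 ± 0.14) and Msmo1 (2.27 ± 0.07). Mesenchymal, pericyte and matrix genes were lower in 6 of 19 (adjusted p = 0.00816), with Postn (-5.16 ± 0.09) and Serpinf1 (-4.08 ± 0.12), and stress response genes in 7 of 14 (adjusted p = 0.00816). Dlx5 was higher in Ge6 by 2.07 ± 0.22, but Dlx1 was lower, with a difference of -0.67 ± 0.19. The adjusted p of Dlx1 was 0.0544 without replicate 1 of L2.2, and 0.120 when at least a 1.2-fold difference was demanded in the test. The fit called 4757 genes, 2277 higher and 2480 lower (2774 and 2064 with all arrays shifted to one median, which turned the majority), and 741 differed at least 2-fold, with 2 arrays on the side of L2.2. Named differences had adjusted p of at most 0.00526, for Dlx1.

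At day 7, interneuron genes differed between the pair in both directions. Gad2 was higher in Ge6 by 4.41 ± 0.11, cholecystokinin, Cck (4.35 ± 0.13), and Gad1, 3.57 ± 0.13, were higher, and Calb2 (-5.76 ± 0.15), Calb1 (-3.36 ± 0.17) and Reln (-2.63 ± 0.16) were lower. Of that list 7 were higher and 4 lower of 15 (adjusted p = 0.028), with a median of -0.018 and a mean of 0.47. Dlx1 differed by 1.03 ± 0.17, and Dlx5 by 0.10 ± 0.19, which did not pass the test. Channels and glutamate receptors were higher in Ge6 in 17 of 27 cases (adjusted p = 2.17e-07), with Gria1 (2.98 ± 0.11) and Scn1a (2.73 ± 0.17). Glutamatergic and dorsal forebrain genes were lower in 6 of 13 (adjusted p = 0.0342), with Pax6 (-3.99 ± 0.10), Slc17a6 (-3.59 ± 0.14) and Neurod1 (-2.79 ± 0.13), while Bcl11b (4.23 ± 0.17) was higher. Astrocyte genes were lower in 14 of 20 (adjusted p = 0.000221, but adjusted p = 0.0643 with an estimated correlation), Gfap (-2.77 ± 0.16) most. The neurofilament genes Nefm (-3.10 ± 0.15) and Nefl (-2.15 ± 0.15) were lower although 25 of 37 pan-neuronal genes were higher (adjusted p = 2.46e-07). Calls came to 5736, 2352 higher and 3384 lower, and 1001 differed at least 2-fold. Among named differences that passed, the highest adjusted p was 4.7e-06, for Dlx1.

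The nonneuronal clone Ge2 was compared with the mean of the 4 others at day 7. Pan-neuronal genes were lower in 36 of 37 cases (adjusted p = 1.43e-20), with Mapt (-6.37 ± 0.11), Dcx (-6.25 ± 0.12) and Tubb3 (-6.00 ± 0.07). Cell cycle genes were lower in 38 of 38 (adjusted p = 9.25e-26) and oligodendrocyte lineage genes in 13 of 18 (adjusted p = 8.11e-06), Olig1 (-5.85 ± 0.13) and Bcas1 (-5.26 ± 0.20) most. The oligodendrocyte list had median differences of -4.03 from Ctx8 and -1.61 from L2.3, but -0.13 from Ge6 and -0.30 from L2.2. Interferon and antigen presentation genes were higher in 10 of 19 cases (adjusted p = 0.00758), with the immunoproteasome subunit Psmb9 (4.08 ± 0.11), Gbp2 (3.69 ± 0.08) and Irf1 (2.99 ± 0.10). Mesenchymal, pericyte and matrix genes were higher in 9 of 19 (adjusted p = 0.0121), with Postn (6.77 ± 0.07), Mgp (4.27 ± 0.11) and Col4a1 (3.81 ± 0.08). Ifitm3, an interferon-induced membrane protein, was higher by 6.74 ± 0.08 and the alarmin Il33 by 5.25 ± 0.10. The astrocyte list split, with 9 higher and 7 lower of 20 (adjusted p = 0.847). There Agt (4.13 ± 0.11) and Aldoc (2.08 ± 0.07) were higher and Gja1 (-6.59 ± 0.08) lower. Dlx1 differed by -4.81 ± 0.14 and Gad1 by 2.46 ± 0.10. By its mean, Gad1 in Ge2 lay below Ge6 (-1.77) and above the 3 others, and Dlx1 lay close to L2.3 (-0.19). The fit called 7474 genes, 3756 higher and 3718 lower, and 1755 differed at least 2-fold. Named differences had adjusted p of at most 1.48e-21, for Gad1.

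The 2 multipotential clones differed in 1629 called genes at day 0, against 4757 for Ge6 and L2.2. Tes and Moxd1 were higher in Ctx8, by 5.84 ± 0.17 and 4.75 ± 0.14, and so was the dorsal forebrain factor Emx2 (2.63 ± 0.22). The collagen chaperone Serpinh1 (-3.79 ± 0.11) and Chchd10 (-3.59 ± 0.10) were lower. Notch pathway genes were higher in 5 and lower in 1 of 14 cases (adjusted p = 0.00453), with Dll3 (1.94 ± 0.10), Hes5 (1.62 ± 0.16) and Hey1 (1.34 ± 0.10). Pan-neuronal genes were higher in 10 and lower in 4 of 37 (adjusted p = 0.0299, but adjusted p = 0.402 with an estimated correlation), Stmn3 (2.39 ± 0.16) most. The astrocyte list was higher in 6 and lower in 1 of 20 (adjusted p = 0.027, but adjusted p = 0.45 with an estimated correlation), with Aldoc (1.26 ± 0.08). Without replicate 1 of Ctx8 the adjusted p was 0.103 for the pan-neuronal and 0.160 for the astrocyte list, and without replicate 1 of L2.3 it was 0.0517 for both. Without dim genes the pan-neuronal list had 0.0713. Cell cycle genes passed in 0 of 38 cases (adjusted p = 0.836). Dlx1 differed by 0.33 ± 0.17 and Gad1 by -0.09 ± 0.13, neither past the threshold. Without replicate 2 of L2.3, Dlx1 differed by 0.56 with an adjusted p of 0.0328. Of the called genes 821 were higher and 808 lower, and 152 differed at least 2-fold. Among named differences that passed, the highest adjusted p was 1.08e-09, for Hes5.

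Whether the change over 7 days of differentiation differed between clones was tested as the difference of day 7 changes, which take in the new medium and the time in culture as well as the loss of FGF2. Against the mean change of the 4 other clones, the change in Ge6 lay higher in 33 of 37 pan-neuronal genes (adjusted p = 1.4e-18), with Stmn3 (4.20 ± 0.18) and Myt1l (3.95 ± 0.15), and in 18 of 27 channels and receptors (adjusted p = 7.3e-08), with Scn1a (3.24 ± 0.20) and Kcnd2 (3.13 ± 0.20). In the GABA and interneuron list 7 differed upward and 4 downward (adjusted p = 0.012, but adjusted p = 0.0531 with an estimated correlation), Cck (4.28 ± 0.15) and Slc32a1 (4.07 ± 0.18) against Calb2 (-5.42 ± 0.17) and Reln (-1.67 ± 0.18). Of the Dlx list 5 of 9 differed upward (adjusted p = 0.00318), with Meis2 (2.41 ± 0.07) and Nkx2-1 (2.35 ± 0.10) beside Dlx1. The cell cycle list differed upward in 33 of 38 cases (adjusted p = 4.07e-07, but adjusted p = 0.246 with an estimated correlation), Top2a (1.47 ± 0.20) most. Astrocyte genes differed downward in 14 of 20 (adjusted p = 1.32e-05, but adjusted p = 0.0632 with an estimated correlation), with Mlc1 (-3.64 ± 0.20) and Agt (-3.56 ± 0.16), and oligodendrocyte genes in 12 of 18 (adjusted p = 0.00451, but adjusted p = 0.2 with an estimated correlation). BMP and TGF-beta responsive genes differed downward in 8 of 13 (adjusted p = 0.00648, but adjusted p = 0.0687 with an estimated correlation) and cholesterol synthesis genes in 15 of 18 (adjusted p = 0.00243, but adjusted p = 0.246 with an estimated correlation). Cell cycle genes had a median change of -1.27 in Ge6, lower than the -1.06 of L2.2 and -0.85 of L2.3, so the upward difference came from Ge2, at -4.62, and Ctx8, at -2.19. That list was lower than at day 0 in Ctx8 (adjusted p = 6.41e-18, but adjusted p = 0.0514 with an estimated correlation) and L2.2 (adjusted p = 1.4e-08, but adjusted p = 0.175 with an estimated correlation). The difference also turned against single clones, by means or list medians, for Top2a, at -0.13 from L2.3, for the cholesterol list, at 0.18 from Ctx8, and for the oligodendrocyte list, at 0.03 from Ge2, while the BMP and TGF-beta list lay at -0.02 from L2.2. The pan-neuronal list lay 2.79 from Ge2 and 2.22 from Ctx8, but 0.99 from L2.3 and 0.58 from L2.2. By its median, the Dlx list lay 1.20 from Ge2 and further from L2.3, but only 0.06 from Ctx8 and 0.10 from L2.2. The median of the GABA and interneuron list lay 0.62 from Ge2, but 0.02 from Ctx8, 0.10 from L2.2 and 0.12 from L2.3. The largest upward differences were Tmem130 (5.50 ± 0.17), Npy1r (5.28 ± 0.11) and Bcl11b (5.16 ± 0.19). Of all genes 6622 were called, 2887 upward and 3735 downward, and 1648 differed at least 2-fold. Named differences had adjusted p of at most 5.94e-08, for Top2a.

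An F test over all 5 clones called 9116 of 12749 genes as changing differently by day 7 in some clone, and 4800 of these had changes at least 2-fold apart. The calls took in 38 of 38 cell cycle genes, 37 of 37 pan-neuronal genes, 18 of 18 cholesterol synthesis genes and 14 of 14 stress response genes. They took in 4 of 9 GABA-A receptor subunits, 3 of 16 microglia and macrophage genes, 5 of 11 endothelial genes and 4 of 10 Schwann and neural crest genes. The list medians of these last 3 cell types, which such cultures could hold, were low throughout, though single members could be higher. The median intensity over the members lay between 11 and 13.4 for microglia, 10.9 and 14.2 for endothelial cells and 10.8 and 14.4 for Schwann and neural crest cells over the 44 arrays. By comparison, 16.3 was the 40th percentile of all values in the table. In Ge6 at day 7 against day 0, 0 of 16 microglia genes rose and 1 fell (adjusted p = 0.982). Endothelial genes rose in 1 of 11 cases (adjusted p = 0.982), and Schwann and neural crest genes rose in 1 and fell in 1 of 10 (adjusted p = 0.982).

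For the lists fixed beforehand, the count of called members was also taken with p-values adjusted over the list alone. Over 380 pairs of list and comparison the 2 counts differed by at most 4, and in 293 pairs not at all. For the pan-neuronal genes of Ge6 at day 7 the count adjusted over the list alone was 36, for the GABA and interneuron list 11 and for the Dlx list 7, against 36, 11 and 7 over all genes. Of 360 list tests 152 passed the threshold with the preset correlation, 102 of these also with an estimated correlation, and 50 were lost. Direction of the test and sign of the median differed in 68 of the tests, 2 of them past the threshold, the glutamatergic list of L2.2 at day 3 and the GABA list of Ge6 against L2.2 at day 7. Shifting all arrays to one median moved the median change of all genes by between -0.16, in Ctx8 at day 7, and 0.13, in Ge6 against the other clones at day 3. Ge6 at day 7 had a median change of -0.06 as deposited and -0.21 after that shift. Within clones with 3 arrays at both days, 128 gene changes were named, and the 126 that passed the test all had the arrays of the later day on one side of those of day 0, while the 2 others overlapped. Chance gives 10% for a gene not chosen by its values, which is no yardstick for genes chosen by the test and in part for the lack of overlap.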

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

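The tests of neurons in the Ge2 cultures, of the Gad1 probe sets, of the amino acid response genes and chaperones, of the single day 0 arrays of L2.2 and of each clone against the others, by list or as a split, were chosen after the results were seen, while the interaction tests and the splits of the arrays were planned.

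Gad1 rose at day 7 more in Ge6 than in the mean of the other clones, by 4.16 in log2, Gad2 by 3.96, Dlx1 by 2.12 and Dlx5 by 0.83. By single clones, Dlx1 changed by 5.0 ± 0.17 in Ctx8 against 3.97 ± 0.17 in Ge6, and Dlx5 by 4.76 ± 0.22 in L2.2 and 3.16 ± 0.19 in Ctx8 against 2.80 ± 0.19 in Ge6, so for these genes the excess over the mean came mostly from Ge2 and L2.3. The sizes for Gad1 and Gad2 rest on day 0 levels near background, and so does that of Dlx5 in Ctx8, which began at 11.4. At day 7 Ctx8 had 566 for Dlx1 and 102 for Dlx5, against 2457 and 867 in Ge6. The test of the day 7 change in Ge6 against that in the others called 6622 genes, and the test of any difference between clones 9116. By list the adjusted p was 0.00318 for Dlx and ventral forebrain factors, 1.4e-18 for pan-neuronal genes and 7.3e-08 for glutamate receptors and channels, all of which also passed with an estimated correlation, at 0.027, 3.48e-05 and 0.000386. It was 0.012 for GABA and interneuron genes, 4.07e-07 for cell cycle, 1.32e-05 for astrocyte, 0.00451 for oligodendrocyte, 0.00648 for BMP and TGF-beta and 0.00243 for cholesterol synthesis genes. With an estimated correlation these had adjusted p of 0.0531, 0.246, 0.0632, 0.2, 0.0687 and 0.246, past no threshold. The median difference of the Dlx list was 1.20 from Ge2 and larger from L2.3, but 0.06 from Ctx8 and 0.10 from L2.2.

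Some lists had a day 7 median in one clone on the other side of 0 from the 4 other clones, among 100 tests of clone and list. With an estimated correlation the adjusted p of the difference was 0.000254 for pan-neuronal genes in Ge2, with a median of -0.11 against 0.49 to 3.29 in the others. For BMP and TGF-beta responsive genes in L2.2 it was 0.0489, with -0.18 against 0.12 to 1.54. With all arrays shifted to one median, Ge6 lay below 0 as well, at -0.03. For stress response genes in L2.3 the adjusted p was 0.0212, with 0.02 against -1.07 to -0.05. Ctx8 differed for the stress list in the direction of L2.3, at a median of -0.05 (adjusted p = 0.00761 with an estimated correlation). After that shift L2.3 lay below 0 like the others, at -0.08, so it did not stand alone there. For cholesterol synthesis genes in L2.2 the adjusted p was 0.00616, with 0.39 against -1.43 to -0.84.

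In the nonneuronal clone Ge2, the rise of Gad1 by day 7 was set against the distance from its Ge2 day 0 to its Ge6 day 7 intensity. That share was 29.1% with the brighter probe set, while the pan-neuronal list did not pass its camera test there (adjusted p = 0.827). Neurons like those of Ge6 in these cultures would carry their other transcripts. Taken were the 23 of 37 pan-neuronal genes at least 8-fold higher in Ge6 at day 7 than in Ge2 at day 0. Their share had a median of -0.0551% (quartiles -0.475% and 0.252%), with Nsg2 (13.43%) and Dpysl5 (13.03%) highest, and 0 reached that 29.1%. The share was not computed for the other Gad1 probe set, so that count of 0 holds for the brighter one only. A smaller Gad1 share could lie below those of Nsg2 and Dpysl5. Cross-hybridisation of a single probe set is argued against by its 2 probe sets, which both rose, by 6.58 ± 0.13 and 2.55 ± 0.13. The second rose much less, so the size of the rise depends on the probe set. A property of the single clone or its culture history stays open as untested.

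Genes of the amino acid and integrated stress response fell by day 7 in Ge2, Ge6 and L2.2, with list medians of -1.97, -1.85 and -2.29 over 31 genes (adjusted p = 0.000242, 0.000164 and 2.23e-06 by limma's camera with an estimated correlation, over 10 tests). Ctx8 had -0.22 (adjusted p = 0.564) and L2.3 -0.01 (adjusted p = 0.564), also by limma's camera, and the clones were not tested against each other for this list. Relief of protein folding stress was assumed to lower the chaperones of the endoplasmic reticulum by a like amount. Under that untested assumption it is argued against by their median over 19 genes of 0.124 in Ge2 and -0.228 in L2.2. In Ge6 that median was -0.586, less than a like fall but beyond the bound set for excluding it, so folding stress stays open there. The chaperone median was also -0.343 in Ctx8 and -0.354 in L2.3 (adjusted p = 0.188 and 0.019, by the same camera test). The amino acid list did not pass in those 2 clones, so the lists did not move together. The list, written after the data were seen and sharing 7 genes with the fixed stress list, had a median intensity of 991, 1033 and 1251 in the 3 clones at day 0 against 368 in Ctx8 and 427 in L2.3, and of 255 to 361 in all 5 at day 7, so the clones lay apart before withdrawal, and why they did, in clone or culture, stays open as untested.

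Cholesterol synthesis genes in L2.2 passed the list test upward at day 7 (adjusted p = 0.0242, but adjusted p = 0.417 with an estimated correlation). A deviating array among the 2 of day 0 is argued against by the medians with either array alone, 0.327 and 0.447. The list lay -1.47 in log2 from the mean of the other clones at day 0 and 0.11 at day 7. A property of this clone or of its culture at day 0 stays open as untested.

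Of 6636 probe sets without a single gene, which the comparisons of genes did not use, 1183 were called with at least a 2-fold change from day 0 to day 7 in Ge6, 865 higher and 318 lower.

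Other splits of the arrays were tried. For Ge6 against the other clones as 1 group, 100 splits, the real one included, were taken at each day. The real labels called the most genes, with 726 against at most 678 at day 0, 3005 against 129 at day 3 and 2892 against 381 at day 7. Most of the other splits mixed sister cultures of different clones, so these counts show that cultures of 1 clone resembled each other and are no independent evidence that Ge6 stood apart more than another clone. Setting Ge2 apart in the same way was not among the splits drawn for Ge6. It called more genes than Ge6, 2254 at day 0, 4179 at day 3 and 3651 at day 7, and 2493 for the day 7 change. L2.2, with 2 arrays, called 1349 at day 0. These fits pooled the other clones, and their counts differ from those of the 15-group fit. Within the same limit, the real labels also called more than each other drawn split for Ge2 at day 7 with 3651 against 381, for the day 7 change in Ge6 with 1953 against 1008 and for any difference between clones with 8971 against 2022. With 3 arrays on each side there are 10 splits, too few for a share under 0.05. The real splits called 7073, 7266, 5959 and 5956 genes at day 3 in Ctx8, Ge2, Ge6 and L2.3 and 7342, 7101, 7215 and 6006 at day 7. They called 5012 for Ge6 against L2.2 at day 7 and 1623 for Ctx8 against L2.3, and the highest of the other splits called 0 in each of these 10 comparisons. Comparisons with the 2 arrays of L2.2 at day 0 were not split.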

How the results depend on the processing

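Leaving out the 3 arrays farthest from their group means was chosen after seeing the data, and the other alternatives were planned. Every total of called genes, and of those at least 2-fold, stayed within 1.5 times its value under array shifts, quantile normalization, dim genes left out, mean of probe sets, array weights, variance trend, fits to the groups compared, blocks, the 3 arrays left out and each of the single arrays left out. With all arrays shifted to one median, 4 counts of 1 direction moved further, lower genes in Ctx8 at days 3 and 7 and in L2.2 at day 3 and higher genes in Ge6 against the other clones at day 3, as given beside those results. Where leaving out an array left L2.2 at day 0 with a single one, that array was assumed to vary like the other groups. Counts moved with every probe set on its own, since 24183 probe sets were then tested, and, for 15 of 18 counts, with a 1.2-fold minimum, since smaller changes no longer count. Dim genes left out meant 9746 genes, and signal over background limits what 3003 others can show.

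With every probe set on its own, called probe sets in Ctx8, Ge2, Ge6, L2.2 and L2.3 numbered 11494, 13173, 10537, 9867 and 9625 at day 3, with 3101, 4579, 2309, 1958 and 1794 at least 2-fold. At day 7 the same clones gave 11795, 13167, 12996, 10669 and 10144, with 3364, 4625, 4584, 2606 and 2097 at least 2-fold. Ge6 against the other clones gave 7814, 12102 and 12739 at days 0, 3 and 7, with 567, 2363 and 2648 at least 2-fold. Ge6 against L2.2 gave 7687 and 9708 at days 0 and 7, with 1265 and 1774 at least 2-fold. Ge2 against the others at day 7 gave 12677 and 2921, Ctx8 against L2.3 2571 and 280, the difference of day 7 changes in Ge6 11222 and 2883 and the F test 15710 and 8298, the latter of each pair at least 2-fold.

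With at least a 1.2-fold change demanded in the test, calls at day 3 in Ctx8, Ge6, L2.2 and L2.3 numbered 4461, 3537, 3310 and 2990, and at day 7 in Ctx8, L2.2 and L2.3 4716, 3905 and 3323. Ge6 against the other clones gave 1457, 4158 and 4158 at days 0, 3 and 7, and against L2.2 1952 and 2723 at days 0 and 7. Ge2 against the others gave 4371, Ctx8 against L2.3 408 and the difference of changes in Ge6 3910. The counts of Ge2 at days 3 and 7, 5476 and 5525, and of Ge6 at day 7, 5455, stayed within 1.5 times.

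The replicate numbers showed no strong pairing of the samples. Deviations of same-numbered arrays had a median correlation of 0.0175 within a clone, over 0.1 in 3 of 43 pairs, and 0.0178 within a day. For arrays with other numbers it was slightly lower, -0.0108 within a clone, over 0.1 in 1 of 86 pairs, and -0.007 within a day. With the number as a block, Ge6 at day 7 had 7508 calls, Ctx8 against L2.3 1656 and the list tests 150 past the threshold. As a random block within clones it gave Ge6 7540 calls, and no call of a named gene changed under either block.

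Directions turned for values that had not passed the test, and the cause was not tested. Dlx1 at day 7 in Ge2 lay between -0.306 and 0.091 with 1 array left out and was 0.255 without the 3 farthest arrays. Gad1 at day 7 in L2.3 lay between -0.014 and 0.107 with 1 array left out, and was -0.055 with all arrays shifted to one median and -0.025 with the mean of probe sets. The test direction turned for stress genes at day 7 in L2.3, with an adjusted p of 0.997 without dim genes, 0.951 with the mean of probe sets and 0.968 to 0.999 with 1 array left out. It also turned at day 7 in Ge6 for Schwann genes, 0.991 with the mean of probe sets and 0.959 to 0.998 with 1 array left out, and for microglia genes, 0.871 to 0.998. Left out singly, arrays gave between 150 and 154 list tests past the threshold and 7249 to 7348 calls for Ge6 at day 7.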

Other observations

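The overlap between the clones and its list tests were chosen after the results were seen, and the genes named for them were chosen after their values were seen.

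By day 7, 143 genes were higher and 105 lower by at least 2-fold in all 5 clones. Independent lists would share 0.0381 and 0.0322, but all clones had the same change of medium and time in culture, so those numbers are no yardstick. Astrocyte genes were over-represented among those higher in all clones, with 8 of 20 measured members (Fisher's exact test over 40 tests, adjusted p = 3.08e-10). They were Aldoc, Apoe, Aqp4, Atp1b2, Clu, Gfap, Mlc1 and S100b, so these were higher also in the clones labelled as neuronal, interneuronal and nonneuronal precursors. Among the genes lower in all clones were 11 of 38 cell cycle genes (adjusted p = 2.77e-13), such as the replication factors Mcm2, Mcm3 and Mcm5 and the mitotic kinases Aurka, Bub1 and Plk1. FGF and ERK targets were there with 7 of 16 (adjusted p = 3.08e-10), namely Ccnd1, Dusp6, Etv4, Etv5, Spry1, Spry2 and Spry4. Fisher's test takes genes as independent, while members of a list can change together, so these adjusted p overstate the evidence. In camera with an estimated correlation, the cell cycle list lost its day 7 call in Ctx8, Ge6, L2.2 and L2.3, and the astrocyte list in Ge6.

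Some genes outside the lists stood among the 10 largest falls of several clones at day 7. Rassf3 changed by -4.63 ± 0.12 in Ctx8, -4.76 ± 0.12 in Ge6 and -4.58 ± 0.12 in L2.3, and the carbonyl reductase Cbr3 by -4.16 ± 0.11, -4.52 ± 0.11 and -5.25 ± 0.11. The matrix metalloproteinase Mmp2 changed by -4.62 ± 0.15 in Ctx8 and -4.42 ± 0.15 in Ge6. The imprinted RNA H19 was lower in Ge6 than in L2.2 at day 0, with a log2 difference of -4.89 ± 0.22, yet it was above the mean of the other clones at day 7, by 4.72 ± 0.16, and its day 7 change exceeded theirs by 5.08 ± 0.22. Plagl1, another imprinted gene, was lower in Ge6 than in the other clones at day 0, with -2.78 ± 0.06.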
